A study of Zea mays with 12 samples.

How the data were processed

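The study measured C-to-U RNA editing in maize (Zea mays) kernels at 15 days after pollination. Plant mitochondria convert selected cytidines of their transcripts to uridine, and the edited base is read as T in cDNA. The groups are kernels of 2 mutant alleles of the nuclear gene dek53, named dek53-ref and dek53-mu1, and a wild type for each, named WT-ref and WT-mu1, with 3 libraries per group and 12 in all. Group and replicate number came from the sample titles.

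Per the labels' protocols, total RNA was treated with DNase I, reverse transcribed, and used as template to amplify 35 mitochondrial genes by PCR. The amplicons of each template were mixed in equal molar amounts, sheared and made into DNA libraries, and the series text gives paired reads of 150 bp. Median depth per gene was far from equal, from 1270 reads (rps12-ct) to 132133 (ccmC) in dek53-ref replicate 1. Depth after PCR and mixing was not taken as a measure of transcript abundance, and no expression was tested. Bowtie2 2.3.5 and SAMtools 1.9 are named per the submitters' processing notes. The counting tool, the source of the gene sequences and the genome build are not given in the sources used here.

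The deposited files hold read counts, not normalized by the authors. Each line gives a gene, a position, the reference base, the depth as a count, and for each base a field of 14 joined values of which the second is that base's read count. Positions count from 1 at the first base of each gene's sequence, and no chromosome coordinates are given because the files use none. A site is written here as gene and position. The sequence of nad4 in the files departs from the reads from position 1402 on, where coverage falls away, so no codon was assigned after it. The name rps12-ct in the files is not explained in the labels, and its single site was left out of the gene classes and codon counts. The dek53 transcript is not among the 35 amplified sequences, so the genotype labels were not checked against it.

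The editing level of a site was T reads as a percentage of C plus T reads. Sites tested were reference cytidines with at least 100 C plus T reads in every library and a mean level over the 12 libraries of at least 5%. Of 7171 cytidines, 6924 had that coverage and 523 in 34 genes met both conditions. The lowest C plus T count behind a site in a library was 110, and the median over sites of the mean count was 8569. Intervals and standard errors rest on the spread between libraries. PCR reads without molecular identifiers are not independent molecules, so read numbers overstate the precision.

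The T and C counts of each site were fitted with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with an effect for each library and an effect of group on the odds of editing, in 1 fit over the 12 libraries. A site was called changed at a Benjamini-Hochberg adjusted p under 0.05 and a difference of group means of at least 10 percentage points. The comparisons were each mutant against its own wild type, both mutants pooled against both wild types, the difference between the allele effects, and the wild types against each other. Overlaps and gene classes were tested with Fisher's exact test (SciPy 1.17.1), and mean levels with exact permutation tests, for which 3 libraries against 3 cannot give a p under 0.1. Counts were simulated at the real coverages and the WT-ref levels, with levels near either end of the scale moved inward and spread set from the replicate pairs. Differences between amplicon pools were not simulated, nor wild-type levels of 100%. On these counts the edgeR test passed 100% of the sites changed by 10 or 20 points and 0.929% of the 323 unchanged sites. With the 10-point rule added, 30 of 45 falls and 18 of 31 rises of 10 points were called, and all of those of 20 points. Because nearly every change passes at this depth, the 10-point rule sets most calls.

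Nothing in the labels says that the libraries of a group came from separate plants. The share of depth taken by a gene varied little within a group, with a median SD over genes of 0.0433 on the log2 scale, against 0.552 between the 4 groups, and the second was larger in 35 of 35 genes. The p-values therefore measure only the spread between these libraries, which may be technical, and a difference between amplicon pools cannot be separated from one between genotypes within an allele. The squared differences of a pair of libraries averaged 1.60 to 3.60 times the binomial variance, which repeat libraries of a single pool could also give. Each library was counted as a replicate because the titles number them so.

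Named sites followed a rule fixed before the data were examined: for each allele the 15 largest falls and 5 largest rises among called sites, called sites under 2% in the mutant and at 20% or more in the wild type, the 5 largest called differences between alleles and between wild types, and in each class the gene with the most called sites. Sites named outside it are said to be so. Gene classes fixed beforehand were respiratory complexes I, III, IV and V, cytochrome c maturation, ribosomal proteins, and others (mttB and matR). Alternatives fixed at the same time were limma 3.58.1 on log2 odds with a pseudocount of 0.5, DESeq2 1.42.0 on the same counts, a quasi-binomial model per site, coverage minimums of 20 and 1000, level minimums of 1% and 10%, difference minimums of 5 and 20 points, all bases as denominator, sites within 25 bases of an end left out, the replicate number as a block, a fit on the groups compared, and each library left out in turn. Added after the data were seen were leaving out sequence shared by gene pairs, keeping only genes with a mitochondrial intron, subtracting the median change of a gene with at least 4 sites from each of its sites, and leaving out genes whose median differed by 10 points or more between the wild types. Of the 523 sites, 6 lie in sequence that rps2A shares with rps2B or rps3 with rpl16, where reads could be placed on either.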

Results

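Editing was measured in 12 libraries of pooled mitochondrial amplicons from maize kernels, 3 for each of dek53-ref, WT-ref, dek53-mu1 and WT-mu1. dek53 is a defective kernel locus that encodes a pentatricopeptide repeat protein, a family of nuclear-encoded RNA-binding proteins that select editing sites in organelle transcripts. Each library held between 338332702 aligned bases (dek53-mu1 replicate 2) and 603698927 (dek53-ref replicate 1), and the median depth per position was between 4957 and 8039 reads. The lowest median depth of a gene was 899 reads, in rps12-ct of dek53-mu1 replicate 2, and the highest was 132133, in ccmC of dek53-ref replicate 1. At cytidines with a mean level under 1%, which leaves out more than the 523 editing sites, C was read as T in 0.0677% of reads on average. The range over libraries was 0.0585% to 0.0723%. The other 11 kinds of mismatch averaged between 0.0019% and 0.0213%.

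Averaged over the 523 sites, editing was 61.2% ± 0.0769 in WT-ref, 62.0% ± 0.0608 in dek53-ref, 65.2% ± 0.0480 in WT-mu1 and 62.6% ± 0.0129 in dek53-mu1 (SD, n = 3 each). The mean level was thus 0.768 points higher in dek53-ref than in WT-ref (SE 0.0566), and lower in dek53-mu1 than in WT-mu1, by -2.55 points (SE 0.0287). In both comparisons the 3 libraries of one group lay outside the range of the other, and the two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. The pooled difference was -0.891 points (SE 0.0317), with an exact permutation p of 0.1 when libraries were permuted within families. That value is not the smallest this permutation allows. The alleles changed in opposite directions, so permuting the ref family alone gave differences at least as large. The sign for dek53-ref turned, to -0.253 points, when matR, cox3, rps2A and rps12 were left out, and was -0.0497 over genes with an intron. In the same order, the difference was -2.62 and -0.872 points for dek53-mu1, and -1.44 and -0.461 pooled.

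The comparison of dek53-ref with WT-ref asks which mitochondrial sites differ between mutant and wild type, whether through genotype or amplicon pool. Editing fell at 33 sites in 15 genes and rose at 42 sites in 14 genes. The largest fall was at cox2-638, in the gene for subunit II of cytochrome c oxidase, where editing changes codon 213 from serine to leucine: the level was 70.3% ± 0.200 in WT-ref and 37.3% ± 0.162 in dek53-ref (SD, n = 3), a fall by 33.0 points (SE 0.149, edgeR adjusted p = 2.39e-28). It was followed by nad7-99, which was 57.0% ± 0.113 in WT-ref and 35.6% ± 1.38 in dek53-ref, and nad6-138, which was 62.5% ± 0.418 and 42.3% ± 0.581, both silent sites in genes for complex I subunits. Editing of atp6-515, in the gene for a proton-channel subunit of ATP synthase, was 95.9% ± 0.281 in WT-ref and 77.3% ± 1.35 in dek53-ref. The other 11 of the 15 largest falls were between -14.0 and -17.2 points. They were at nad6-88, nad6-89 and nad6-146, nad9-14 and nad9-356, rps4-290 and rps4-944, atp8-123, ccmFC-1219, cob-1124 and cox2-620. The genes with the most lower sites were nad6 (4 of 15 sites) among complex I genes, cob (3 of 16), the apocytochrome b gene of complex III, cox2 (2 of 23) for complex IV, atp4 and atp8 (2 each) for complex V, ccmFC (4 of 30) for cytochrome c maturation, rps4 (2 of 18) for ribosomal proteins, and mttB (2 of 17) among the others.

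The largest rises in dek53-ref were at cox3-289, from 37.8% ± 0.335 to 71.3% ± 0.343 (33.5 points, SE 0.277, edgeR adjusted p = 3.42e-28), rps2A-514, from 32.7% ± 0.680 to 65.7% ± 0.638, cox3-527, from 38.9% ± 0.356 to 69.0% ± 0.593, rps3-497, from 34.5% ± 0.562 to 62.5% ± 0.431, and cox3-314, from 30.1% ± 0.386 to 57.8% ± 0.389 (SD, n = 3). Of the 42 sites that rose, 9 lay in cox3, 7 in matR, 5 in rps3 and 4 in rps2A. The median change of all 13 cox3 sites was 22.3 points and that of all 5 rps2A sites 25.2 points, and these were genes in which WT-ref had lower levels than WT-mu1. With the median change of each gene subtracted, 32 sites were lower and 19 higher in dek53-ref, against 33 and 42 without, and the largest 5 rises kept 2 of their members past 10 points while the largest 15 falls kept 13.

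The same question in the dek53-mu1 allele gave 77 lower sites in 23 genes and 13 higher sites in 7 genes. The largest fall was again at cox2-638, which was 67.0% ± 0.701 in WT-mu1 and 28.1% ± 0.123 in dek53-mu1 (SD, n = 3), a fall by 38.9 points (SE 0.411, edgeR adjusted p = 4.60e-30). Next came nad2-1409, a proline-to-leucine site near the end of a complex I gene, at 87.3% ± 1.74 in WT-mu1 and 55.5% ± 1.94 in dek53-mu1. This site read 100% in all 6 libraries of the ref family. It was called in neither the pooled comparison (-15.9 points) nor the difference between alleles (31.8 points). Odds of editing cannot be estimated without unedited reads, so the missing calls are no evidence of equal editing. Then followed rps4-980, in the gene of a small-subunit ribosomal protein, at 57.1% ± 0.722 and 28.0% ± 1.52, rps4-944, at 50% ± 0.477 and 24.2% ± 1.10, and ccmFN-1492, in a cytochrome c maturation gene, at 38.2% ± 0.490 and 12.6% ± 0.931. The remaining 10 of the 15 largest falls were between -19.9 and -23.7 points, at rps4-49, rps4-278, rps4-290, rps4-335 and rps4-915, nad9-113 and nad9-223, rps12-289, ccmFN-318 and mttB-532. Lower sites were most numerous in rps4 (14 of 18) among ribosomal protein genes, nad9 (9 of 13) for complex I, ccmFN (6 of 39) for cytochrome c maturation, cox3 (5 of 13) for complex IV, atp8 (5 of 6) and atp9 (5 of 7) for complex V, cob (1 of 16) for complex III and mttB (4 of 17) among the others.

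The largest rises in dek53-mu1 were at rps3-707, from 36.4% ± 0.987 to 72.8% ± 1.92 (36.4 points, SE 1.25, edgeR adjusted p = 3.82e-24), rps3-497, from 40.1% ± 0.231 to 67.4% ± 1.59, rpl16-444, from 47.2% ± 0.155 to 73.3% ± 1.43, nad1-537, from 37.1% ± 0.441 to 59.6% ± 0.952, and rps2B-510, from 19.4% ± 0.779 to 38.3% ± 0.949 (SD, n = 3). With the median change of each gene subtracted, 31 sites were lower and 15 higher in dek53-mu1, against 77 and 13 without. All 5 of the largest rises and 7 of the 15 largest falls stayed past 10 points.

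**Figure D1:**
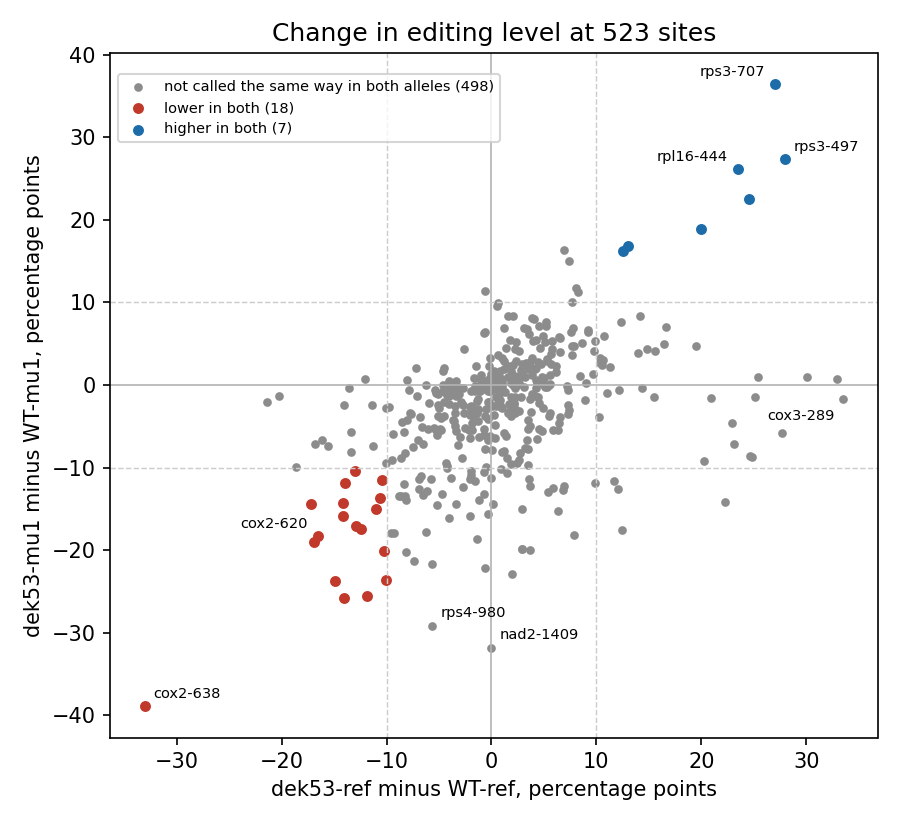
Difference in mean editing level between mutant and wild type at the 523 sites, in percentage points, for dek53-ref (horizontal) and dek53-mu1 (vertical), with dashed lines at 10 points either way. The 18 sites lower in both alleles are red, the 7 higher in both are blue, and cox2-638 lies at -33.0 and -38.9 points.

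Editing was lower in both alleles at 18 sites in 10 genes and higher in both at 7 sites in 5 genes. Independent lists of the same lengths would share 4.86 and 1.04 sites, and the one-sided Fisher's exact p was 2.87e-08 for the lower and 1.57e-05 for the higher sites. The comparisons share no library. The overlap tests treat sites as independent and equally able to change, which they are not. Sites of a gene can shift together, and a level near either end of the scale leaves no room for a change of 10 points that way. The expected overlaps may therefore be too low and the p-values too small. The lower sites were nad3-344, nad6-146, nad9-14, nad9-113 and nad9-356 of complex I, cob-725 of complex III, cox2-620 and cox2-638 of complex IV, atp4-56, atp4-59, atp8-58 and atp8-123 of complex V, ccmFN-1492 and ccmFN-1505 of cytochrome c maturation, rps4-290 and rps4-944 of the ribosome, and mttB-373 and mttB-532, in a gene for a membrane transport protein. At cox2-620, which like cox2-638 changes a serine codon to leucine, the level was 82.4% ± 0.126 in WT-ref and 65.8% ± 0.938 in dek53-ref, and 90.4% ± 0.250 in WT-mu1 and 72.1% ± 0.248 in dek53-mu1 (SD, n = 3). At ccmFN-1492 it was 16.8% ± 1.19 and 4.97% ± 0.195, and 38.2% ± 0.490 and 12.6% ± 0.931, in the same order. No called site fell from 20% or more to under 2% in either allele. Of the 18 lower sites, nad3-344 and nad9-14 lie within 25 bases of an end, and nad3-344 had as few as 218 C plus T reads in a library. Without sites near an end, 16 sites were lower in both alleles. The 7 higher sites were nad1-537, rps2B-510, rps3-497, rps3-707, rps3-1066, rpl16-444 and matR-92, of which nad1-537, rps2B-510 and rpl16-444 are silent. Of these 25 sites, nad3-344, cob-725, atp4-56, atp4-59, atp8-58, ccmFN-1505, mttB-373, rps3-1066 and matR-92 lie outside the naming rule and were listed after their values were seen.

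With the median change of each gene subtracted, 6 sites were lower in both alleles, of which 5 were among the 18 (cox2-620, cox2-638, ccmFN-1492, mttB-373, and nad3-344, which lies near an end), and 5 were higher. Independent lists would then share 1.9 and 0.545 sites (one-sided Fisher's exact p = 0.00796 and 8.68e-05). Over genes with an intron alone, 2 sites were lower in both and 4 higher in both (one-sided Fisher's exact p = 0.108 and 9.61e-07). These overlap tests also treat sites as independent and equally able to change, so the limits given above hold here too.

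**Figure D2:**
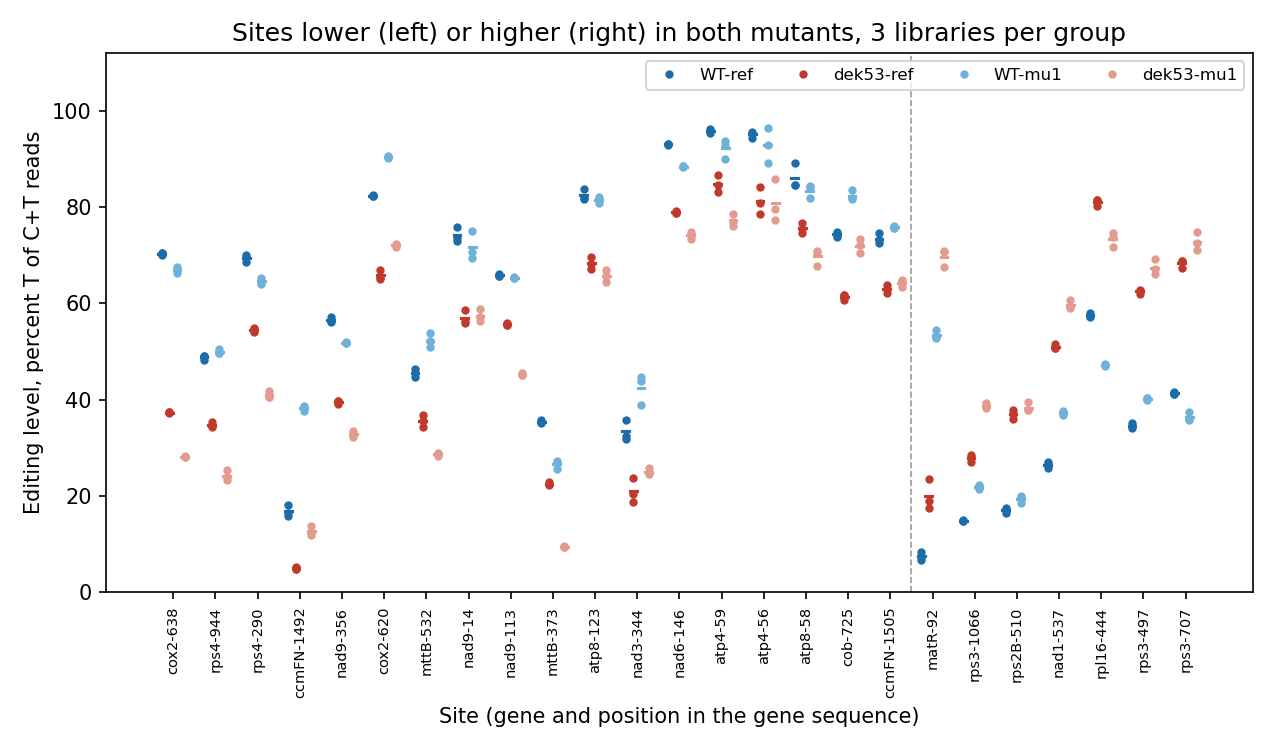
Editing level, as T reads in percent of C plus T reads, at the sites lower (left of the dashed line) or higher (right) in both alleles, with a point for each of the 3 libraries of a group and a bar at their mean. At every site shown, both mutant means lie at least 10 points from the mean of their own wild type, for example 37.3% against 70.3% and 28.1% against 67.0% at cox2-638.

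By gene class, the sites lower in both alleles were 5 of 186 in complex I, 1 of 16 in complex III, 2 of 42 in complex IV, 4 of 48 in complex V, 2 of 125 in cytochrome c maturation, 2 of 73 in ribosomal proteins and 2 of 32 in the others. No class differed from the rest, and the smallest adjusted p was 0.512, for complex V (Fisher's exact test, adjusted over 7 classes; sites of a gene are not independent). The same test was run on further lists after their counts were seen. Sites higher in both alleles were 5 of 73 in ribosomal protein genes, against 0.444% of sites elsewhere (Fisher's exact adjusted p = 0.00548; 0.0648 and 0.066 with a minimum of 5 or 20 points). Sites lower in dek53-ref gave no adjusted p under 0.511 (complex III, 3 of 16). Sites lower in dek53-mu1 were 16 of 48 in complex V, 18 of 73 in ribosomal proteins and 18 of 186 in complex I. The shares were above those of sites elsewhere in complex V (33.3% against 12.8%) and ribosomal proteins (24.7% against 13.1%), and below in complex I (9.68% against 17.5%; Fisher's exact adjusted p = 0.00581, 0.0462 and 0.0462). None of those 3 passed with gene medians subtracted, where each Fisher's exact adjusted p was 1. With a minimum of 5 points it was 0.453 for ribosomal proteins and 0.0585 for complex V, and with 20 points 1 for complex V and complex I.

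Of the 18 sites lower in both alleles, 13 were at a second codon position, 72.2% against 50% of the 504 other sites with a reading frame (Fisher's exact adjusted p = 0.365). Only atp8-123 was silent, against 96 of the 504 (Fisher's exact adjusted p = 0.438). Pentatricopeptide repeat proteins bind bases upstream of the edited cytidine, so the bases from 25 before to 5 after each site were compared. In 120 tests none passed adjustment and 5 had an unadjusted Fisher's exact p under 0.05, where at most 6 are expected by chance. The smallest was for G at 7 bases before the site, present at 11 of the 18 lower sites and 110 of the other 504 (Fisher's exact p = 0.000494, adjusted p = 0.0593).

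Pooling both mutants against both wild types gave 41 lower and 19 higher sites. The lower sites included 5 each in rps4, nad9 and ccmFN and 4 each in nad6 and atp8, and the higher sites included 3 each in rps2A, cox3, rps3 and rpl16. The largest pooled fall was at cox2-638, by -35.9 points (SE 0.218, edgeR adjusted p = 3.77e-33), and the largest pooled rise was at rps3-707, by 31.7 points. With gene medians subtracted, 23 sites were lower and 10 higher, of which 19 and 9 were called without it.

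Whether the alleles differ was tested on the difference itself, the change in dek53-ref minus that in dek53-mu1. It passed at 80 sites, being positive at 75 in 22 genes and negative at 5. The positive sites included 12 each in cox3 and rps4 and 8 each in nad9 and ccmB. The largest was at cox3-754, which was 42.8% ± 3.98 in WT-ref, 65.1% ± 1.56 in dek53-ref, 72.7% ± 1.22 in WT-mu1 and 58.6% ± 2.08 in dek53-mu1 (SD, n = 3), a difference of 36.4 points (SE 2.83, edgeR adjusted p = 1.39e-14). The next were also in cox3, at positions 289, 413, 314 and 764, with 35.2, 33.5, 33.5 and 33.3 points. The 5 negative sites, nad2-303, nad3-185, nad6-138, nad7-99 and ccmFC-1219, were listed after their values were seen, apart from the 3 that the rule names, nad6-138, nad7-99 and ccmFC-1219. At nad7-99 the change was -21.3 points in dek53-ref and -2.06 in dek53-mu1. Another 4 sites, rps4-1031, ccmFC-160, cox3-311 and cox3-754, were higher in dek53-ref and lower in dek53-mu1, where independent lists would share 6.18; the first 3 were listed after their values were seen. With gene medians subtracted, 18 differences were positive and 11 negative, of which 18 and 5 were called without it.

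The wild types differed from each other at 95 sites, with WT-mu1 higher at 73 in 21 genes and lower at 22 in 13 genes. This comparison gives the variation between families against which the mutant changes stand, and it involved more sites than either allele. The 5 largest differences were all in matR, a gene for a maturase-related protein that lies within an intron of nad1: matR-1877 was 13.5% ± 0.366 in WT-ref and 93.6% ± 0.479 in WT-mu1 (SD, n = 3), a difference of 80.1 points (SE 0.348, edgeR adjusted p = 9.28e-33), and matR-1895, matR-1751, matR-1885 and matR-1124 differed by 77.1, 76.8, 74.2 and 72.2 points. WT-mu1 was higher at 13 of 15 matR sites, 12 of 13 cox3 sites and 4 of 5 rps2A sites, and the median differences of these genes were 68.0, 27.3 and 34.6 points, with 11.1 in rps12. In matR the libraries of dek53-ref were also low, with a median of 19.9% against 9.90% in WT-ref, 77.2% in WT-mu1 and 81.5% in dek53-mu1. With gene medians subtracted, 31 sites were lower and 34 higher in WT-mu1.

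**Figure D3:**
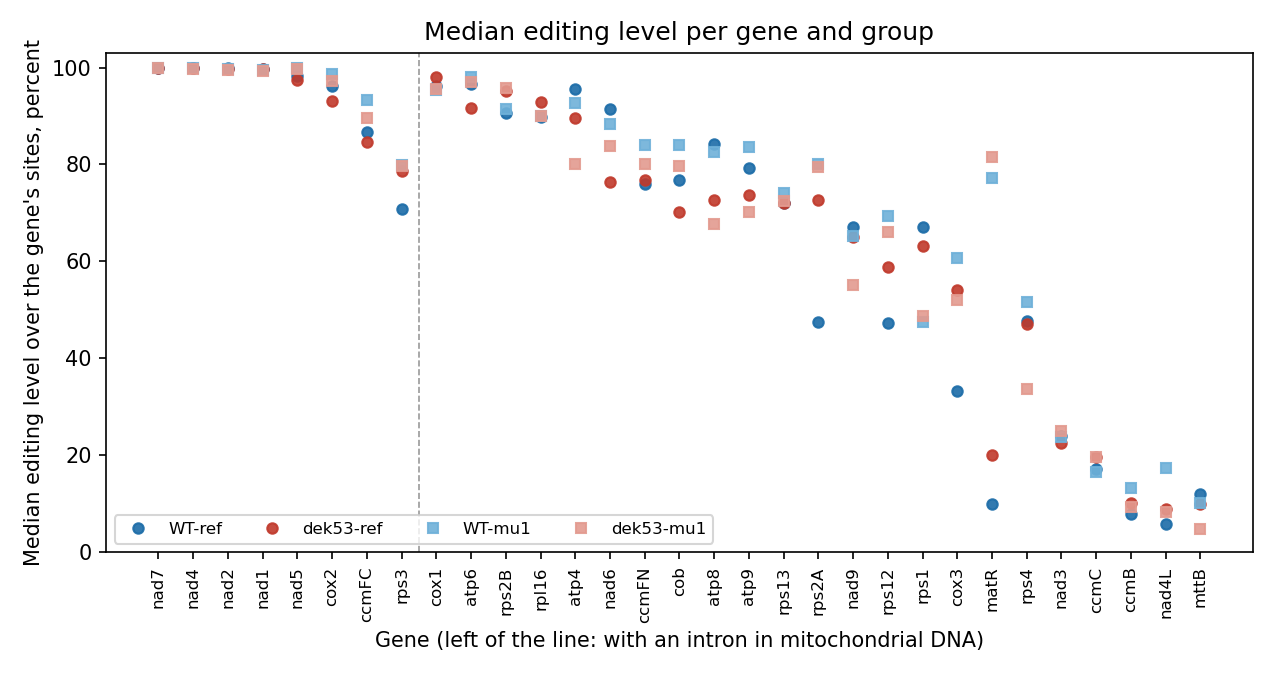
Median editing level over the sites of each gene, in percent, for the 31 genes with at least 4 sites, by group (circles for the ref family, squares for the mu1 family). Left of the dashed line are the 8 genes with an intron in mitochondrial DNA, with medians near 100% in nad1, nad2, nad4, nad5 and nad7, and matR shows the widest gap, from 9.90% to 81.5%.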

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

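All tests of explanations in this part, the splits of the libraries included, were chosen after the results were seen.

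The change from wild type to mutant differed between the alleles at 80 sites by the test of that difference. The wild types differed by 10 points or more at 39 of them and the mutants at 39, and at 28 only the wild types did. The change was more positive in dek53-ref at 75 sites and more negative at 5. The largest were in cox3, where the difference was 36.4 points at cox3-754, 35.2 at cox3-289, 33.5 at cox3-413, 33.5 at cox3-314 and 33.3 at cox3-764; at cox3-289 the mutants were at 71.3% and 66.9% and the wild types at 37.8% and 68.6%, so most of that difference is the low level in WT-ref. Of 100 splits of the libraries within families, 2 gave as many sites, the real one with 80 and another with 81; the latter kept the real grouping of the mu1 family, whose changes then enter the difference, so the splits do not settle whether chance gives as many. With the gene's median difference subtracted, 23 of the 80 sites stayed past 10 points, 17 of them by more than the SE. Of the 23, 2 are in genes with too few sites for a median, which leaves a gene-wide shift open there. Another 9 are in genes whose median was under 1 point, so the gene as a whole shifted little. In the remaining genes 9 sites, picked because they stayed, were past 10 points by more than the SE. A shift of equal points at all sites of a gene is not the whole cause at these 9. A shift in proportion to the level was not tested here and stays open. At the other 57 sites the median difference went from 14.5 to 4.25 points. These are the sites that dropped under 10 points, so the choice itself lowers that median. A shift of the whole gene stays open for them and is not tested by it. The 5 cox3 sites are among them, with 7.33, 6.14, 4.47, 4.43 and 4.25 points left in the order above. They were named for their size and not for this drop, so in cox3 most of the difference was shared by the gene's sites. A difference between the alleles or families was not tested apart from the pools and stays open.

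The sites of matR, cox3, rps2A and rps12 were lower in WT-ref as whole genes, and these hold 32 of the 95 called differences between the wild types. Reads shared between gene sequences do not explain it, since 0 of the 32 called sites in these genes lie in a stretch shared with another of the 35 sequences. A share of unedited template in some amplicons stays open: it would give the sites of a gene about the same ratio of WT-ref to WT-mu1, and over sites at 20% or more in WT-mu1 the ratio ranged from 0.489 to 0.607 in cox3, 0.0758 to 0.226 in matR, 0.450 to 0.660 in rps2A and 0.491 to 0.962 in rps12, but 0 of the 4 genes had an SD of its logarithm above the highest of 15 other genes without an intron (0.408), and only cox3 was at or below their median (0.0588 against 0.0934). Genomic DNA as part of the cause stays open: 0 of the 4 genes have an intron, against 8 of the 27 others (two-sided Fisher's exact p = 0.55), too few genes to decide, and the 33.1 points by which wild-type medians were higher in genes with an intron (permutation p = 0.0288) compare genes and not the wild types. Unedited precursor RNA, and a biological difference between the families, were not tested and stay open.

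The 18 sites lower in both alleles were weighed against a shift of whole genes and against pools that vary with no tie to genotype. For 5 of them, picked because they stayed past 10 points, a shift by the same number of points at all sites of a gene is not the whole cause: the smallest fall left in either allele was -11.2 points, at mttB-373 in dek53-ref (SE 0.292), and cox2-638 kept -31.0 and -37.6. A shift in proportion to the level stays open for part of them. In proportion, cox2-638 and ccmFN-1492 fell most of their genes' sites in both alleles, but 3 and 2 mttB sites fell more than mttB-373 in dek53-ref and dek53-mu1. In the same order, 1 and 4 cox2 sites fell more than cox2-620, and 1 and 0 nad3 sites more than nad3-344. For the other 13 the median fall went from -15.0 to -7.25 points in dek53-mu1 and from -13.9 to -9.81 in dek53-ref. These are the sites that did not stay past 10 points in both alleles, so the choice itself lowers the fall left. The gene medians also include the called sites. A shift of the gene stays open for the 13 and is not tested by these values. Pools that vary independently from site to site would leave the changes of the alleles uncorrelated within genes. Across 517 sites, centred within genes, Pearson's r was 0.584 and Spearman's rho 0.515 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without the 2 sites farthest from the median r was 0.544, and sites are not independent replicates. The permutation exchanged sites within genes, so it cannot exclude pools that shift a gene in proportion to its levels. Such pools could also make the changes correlate. A direct effect of dek53 on these sites remains a hypothesis, along with such pools and a delay of kernel development in the mutants, which was not tested.

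For dek53-ref the real grouping gave 75 called sites and the highest of the other splits 0, for dek53-mu1 90 and 0, and for the wild types 95 and 0; in each case 1 of 10 splits reached the real value, and 10 splits are too few for a share under 0.05. For the pooled comparison 1 of 100 splits, the real one, gave as many as 60 sites and the highest other gave 23. The other splits were drawn at random from those possible within families. If the libraries of a group repeat a single pool, splits that mix groups must call fewer sites. The result therefore does not exclude chance, and a chance difference between amplicon pools was not tested by it.

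Some positions with C-to-T mismatches were in no comparison. At 22 positions the mean level was 5% or more but a library had too few reads, and at 233 positions the mean level was between 1% and 5%. In the counts of all positions at a mean of 1% or more in the libraries with at least 100 reads there, C-to-T had 776 and no other mismatch more than 6.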

How the results depend on the processing

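The restrictions to genes with an intron, the removal of genes shifted between the wild types, the subtraction of gene medians, the removal of shared sequence and the class tests on lists other than the sites lower in both alleles were chosen after the data were seen; the other alternatives were planned. Counts are given as lower and higher, in the order dek53-ref, dek53-mu1, pooled, difference between alleles, wild types, both alleles.

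Limma, DESeq2, the quasi-binomial model, the coverage and level minimums, the denominator, the removal of sites near ends or in shared sequence, and the fit on only the groups compared (which for the pooled and allele comparisons is the fit on all libraries) kept every count within 1.5 times. The 50 pairs of a named site and its comparison, at 44 sites, kept their direction and call under each test, denominator, block and left-out library. The smallest difference that counts moved every count: with 5 points the counts were 84 and 99, 145 and 47, 104 and 71, 29 and 144, 49 and 152, 59 and 28, and with 20 points 3 and 17, 13 and 4, 1 and 4, 0 and 25, 3 and 39, 1 and 4, which the rule's own construction explains. Over genes with an intron they were 10 and 8, 12 and 4, 4 and 4, 3 and 8, 10 and 16, 2 and 4, from fewer sites. Without the 4 shifted genes, the higher sites were 20 in dek53-ref, 9 pooled and 41 between the wild types. With gene medians subtracted, the counts that moved were 19 higher in dek53-ref, 31 lower in dek53-mu1, 23 and 10 pooled, 11 and 18 between alleles, 34 higher between the wild types, and 6 lower in both alleles, of which 18, 29, 19 and 9, 5 and 18, 31, and 5 were called without it; the cause was not tested beyond the shift itself.

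Leaving out each library in turn gave 29 to 32 and 40 to 43 sites in dek53-ref, 76 to 79 and 12 to 14 in dek53-mu1, 39 to 42 and 19 to 21 pooled, 5 to 6 and 72 to 77 between alleles, 20 to 24 and 73 to 79 between the wild types, and 16 to 19 and 7 in both alleles. With the replicate block the counts were 33 and 42, 77 and 13, 41 and 19, 5 and 75, 22 and 73, and 18 and 7, so the block changed no count. Libraries with the same number did not deviate together in the ref family (correlations -0.402, -0.193 and -0.148). In the mu1 family the correlations were weakly positive (0.199, 0.0854 and 0.0367). A library correlated best with its own number in 0 of 3 cases in the ref family and 2 of 3 in the mu1 family. With 3 libraries per group, whether the numbers pair the libraries stays undecided in the mu1 family.

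The difference in mean level for dek53-ref was 0.613 with a coverage minimum of 20, 0.929 with 1000, 0.592 with a level minimum of 1%, and turned to -0.0497 over genes with an intron and -0.253 without the shifted genes, in which cox3 and rps2A had risen. For dek53-mu1 these were -2.71, -2.17, -1.81, -0.872 and -2.62, with -2.76 for a level minimum of 10% and -2.49 without sites near ends. For the wild types the moved values were 3.83 with a coverage minimum of 1000, 2.92 and 4.25 with level minimums of 1% and 10%, 1.24 over genes with an intron and 1.46 without the shifted genes. The pooled value was -1.05 and -0.619 with coverage minimums of 20 and 1000, -0.607 and -1.004 with level minimums of 1% and 10%, -0.821 without sites near ends, -0.461 over genes with an intron and -1.44 without the shifted genes. Leaving out a library gave 0.729 to 0.806, -2.57 to -2.53, 3.90 to 3.98 and -0.910 to -0.872. Of the classes tested on further lists, 0% of complex V sites were lower in dek53-mu1 with 20 points, and 5.48% of ribosomal protein sites were lower in it with gene medians subtracted, below the share of sites elsewhere in each case; the cause was not tested. With 5 points, 35.4% of complex V sites and 50% of complex III sites were lower in dek53-ref, above the share elsewhere (Fisher's exact adjusted p = 0.00412 and 0.00485). Depth limits which sites enter: with a coverage minimum of 1000 the lower sites were 23 in dek53-ref and 55 in dek53-mu1, against 33 and 77.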

Other observations

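The test in this part was chosen after the result was seen, as were the sites described.

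Of the 522 sites with a reading frame, 425 changed an amino acid and 97 were silent, and 265 lay at a second codon position. The most frequent changes were serine to leucine (101 sites), proline to leucine (86), serine to phenylalanine (62) and proline to serine (60). Sites that create a start or stop codon were read separately. nad1-2, which turns a threonine codon into a start codon, was edited at 97.8% ± 3.72 in WT-ref, 93.5% ± 3.78 in dek53-ref, 99.1% ± 1.56 in WT-mu1 and 94.3% ± 3.25 in dek53-mu1 (SD, n = 3), on as few as 37 reads, and was below the coverage minimum. The stop codon of atp6, made at atp6-1186, was edited at 97.7% ± 0.173, 93.1% ± 0.971, 98.4% ± 0.226 and 97.8% ± 0.554 in the same order. The stop codon at rps1-505 was edited at 59.4% ± 4.39 and 59.7% ± 2.79 in the ref family and 29.6% ± 1.03 and 31.4% ± 2.29 in the mu1 family. rpl16-79, a glutamine codon turned into a stop at codon 27, was edited at 84.6% ± 0.462, 91.8% ± 0.234, 91.5% ± 0.487 and 88.0% ± 0.234. It lies in the 152 bases that rpl16 shares with rps3, where reads could be placed on either gene.

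One site came close to losing its editing in both alleles from a low wild-type level. At ccmB-424, which changes codon 142 from arginine to cysteine in a cytochrome c maturation gene, editing was 7.17% ± 0.274 in WT-ref and 0.622% ± 0.0804 in dek53-ref, and 13.3% ± 0.156 in WT-mu1 and 0.0512% ± 0.0252 in dek53-mu1 (SD, n = 3). The last value is below the mean background of 0.0677% at cytidines with a mean level under 1%. At least 13783 reads covered the site in every library of dek53-ref and 34337 in every library of dek53-mu1.

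Of the 233 positions with a mean level between 1% and 5%, 128 (54.9%) were silent. A fall of 5 points or more occurred at 1 of them in dek53-ref and 1 in dek53-mu1, and a rise of that size at 3 and 1.

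A hypothesis that sites higher in both alleles are more often silent was tested. Silent sites were 3 of the 7, against 94 of the 515 others with a reading frame (18.3%; two-sided Fisher's exact p = 0.123), so no difference was detected with 7 sites.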
